A study of Mus musculus with 18 samples.

How the data were processed

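RNA was measured on 18 Affymetrix Mouse430_2 arrays. Per the labels, motoneurons from the spinal cord of mouse embryos at embryonic day 12.5 were enriched by panning for the p75 receptor and grown for 7 days in microfluidic chambers. Such chambers let axons grow through narrow channels into a compartment of their own. BDNF was given at 20 ng/ml on the axonal side, and CNTF at 5 ng/ml on both sides. RNA was taken separately from the somatodendritic and the axonal compartment, amplified linearly in 2 rounds and labelled with biotin. Each compartment had 3 wild-type, 3 empty vector and 3 Smn knockdown arrays, and the last carried a lentiviral short hairpin RNA against Smn.

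The deposited values are log2 expression values, 45101 probe sets on each array, between 2.541 and 15.03. The software that made them is not given in the sources used here. The values show that the authors brought the arrays of each compartment to a common distribution, separately for the 2 compartments. Sorted values differed by at most 0.0048 among the somatodendritic and 0.0125 among the axonal arrays. The median was 5.774 in the somatodendritic and 5.948 in the axonal arrays, and the SD over probe sets was 2.255 and 1.873. Levels and tests across the compartments therefore compare values that were normalized apart.

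Probe sets were assigned to genes with the platform annotation, and gene names were checked by gene identifier against a reference gene table used for names only. Of the probe sets, 34958 named 1 gene, 932 named several and 9211 named none. The probe set with the highest mean over the 18 arrays stood for its gene, which gave 18191 genes, 9008 of them with more than 1 probe set. The 64 control probe sets were left out, as were 11 probe sets that lacked a value on some arrays. No filter on dim probe sets was applied.

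Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Comparisons within a compartment used its 9 arrays. Comparisons between compartments, and the interaction that tests whether the knockdown effect differed between them, used all 18 arrays with 1 mean per group. The standard error (SE) printed beside a log2 difference is limma's. All comparisons rest on 3 arrays per group, or 6 where both control groups were averaged, and this number limits their precision. Nothing in the labels says that the arrays of a group came from separate cultures, so every p-value measures the spread between arrays only. The titles of all knockdown arrays follow another scheme (Nr with a running number) than those of all control arrays (Gr with a number), and nothing in the labels says whether the knockdown arrays were handled apart. The numbers in the array titles did not pair the arrays. Of 15 correlations between arrays with the same number, 1 exceeded 0.1, and they ranged from -0.19 to 0.23.

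A background level was set on each array as the 95th percentile of 147 probe sets for genes of tissues absent from spinal cord, such as olfactory receptors. A gene counted as above background in a group when it exceeded that level on every array of the group. Otherwise the group is called dim, or at, near or below background, for that gene, though single arrays may exceed the level. Where 1 of the groups compared was at or below background, the fold is given as a lower bound against that level ("at least"). Where both groups were, no fold is given. For arrays, signal over background takes the place of sequencing depth.

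The comparisons, the tests, 26 gene lists and the rule for named genes were fixed before the data were examined. The rule took genes at adjusted p under 0.05 whose arrays did not overlap between the groups. Of these, the 10 largest rises and the 10 largest falls were named for both knockdown comparisons and for axonal against somatodendritic controls, and 3 and 3 for the others. Clone-like names were skipped. Where no gene passed, the 5 with the lowest p were named. Smn1 and up to 4 members with the lowest p of each list described were added. The condition on non-overlap was not applied to the interaction, which has 4 groups. Folds of list members follow the same bounds.

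Lists were tested with camera, with its preset correlation of 0.01, and adjusted over the 26 lists. Camera with a correlation estimated from the data was run beside it, and fry, which tests whether the genes of a list move on balance one way. Because members near background cannot fall, the median of a list is also given with such members at their bound.

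On simulated data, genes were shifted by a known amount on arrays without a group difference, 100 genes for each size. A log2 change of 1 was recovered for 94% of genes in the somatodendritic knockdown comparison and for 1% in the axonal one. A log2 change of 2 was recovered for 100% and 24%. For axonal against somatodendritic controls, 58% and 80% were recovered, with 33 wrong calls, and for the interaction 11% and 45%, with 24 wrong calls. For axonal against somatodendritic knockdown arrays, 26% and 73% were recovered, with 35 wrong calls. Fits across the compartments pool the unequal spreads of both. In each of them more simulated calls were wrong than the threshold on the adjusted p allows, so their calls and adjusted p are less certain than stated.

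The same results were also computed with quantile normalization of all 18 arrays together, centring on the median, the brighter genes only, all probe sets, probe sets without _x_at and _s_at endings, eBayes with trend and robust, arrayWeights and a minimum of 2-fold. They were further computed with a fit on 6 or on 18 arrays, another control group, the title number as a block, and leaving out each array in turn. Chosen after the data were seen were the level of the hybridisation spikes as a covariate, leaving out the 2 axonal arrays least correlated with the somatodendritic controls, a restriction to genes above background, the list tests under other scalings, and the difference in knockdown effect between compartments with each dim group at its bound. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3.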

Results

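Gene expression was measured on 18 arrays of RNA from cultured mouse motoneurons, taken from cell bodies with dendrites (somatodendritic) and from axons. In each compartment there were 3 wild-type arrays, 3 with an empty lentiviral vector and 3 with a short hairpin RNA against Smn, the gene whose human counterpart is lost in spinal muscular atrophy. On each somatodendritic array 10396 to 11369 of 18191 genes lay above the background level. On the axonal arrays these were 8916 to 10046 genes in wild-type, 7071 to 10015 in empty vector and 6120 to 7312 in Smn knockdown cultures. Pairs of arrays within a somatodendritic group correlated at 0.994 or more across genes. Within axonal groups r lay between 0.84 and 0.90 for wild-type, 0.78 and 0.88 for empty vector and 0.74 and 0.80 for knockdown arrays. The lowest correlations with the somatodendritic controls were those of axonal knockdown replicate 1 (0.539) and, among axonal controls, empty vector replicate 2 (0.705). The hybridisation spikes BioC and BioD averaged 10.62 (SD 0.08, n = 3) on the log2 scale in somatodendritic wild-type arrays and, in the axonal arrays, 12.66 (SD 0.15) for wild-type, 13.40 (SD 0.73) for empty vector and 13.49 (SD 0.18) for knockdown. The difference between the 3' and 5' probe sets of Gapdh, a sign of RNA quality, was 3.99 to 4.12 in the somatodendritic knockdown arrays, 3.53 to 3.68 with the empty vector and 3.11 to 3.61 in wild-type arrays.

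**Figure D1:**
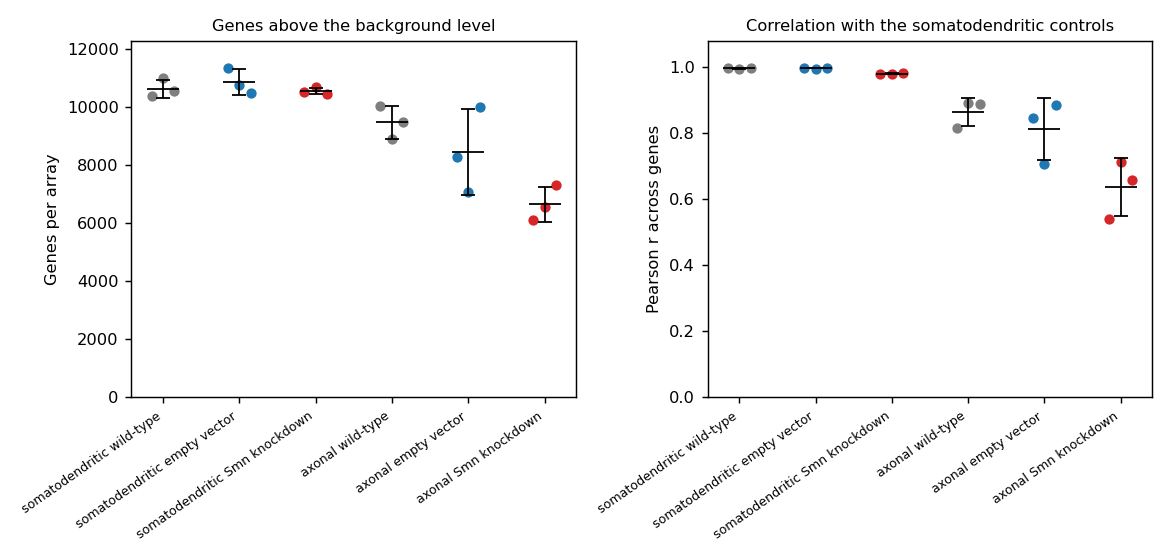
Number of genes above the background level (left) and Pearson r across genes with the mean of the somatodendritic controls (right), for each of the 18 arrays by group. Points are arrays, and black bars are the mean and SD of 3 arrays. The axonal knockdown arrays lie at 6120 to 7312 genes and r of 0.539 to 0.712, and axonal empty vector replicate 2 lies within these ranges, at 7071 genes and 0.705.

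The first question was whether the target transcript fell. Smn1, which encodes the survival motor neuron protein, was read by 1 probe set, and on 17 of the 18 arrays its value lay below the background level. The exception was axonal empty vector replicate 1, at 7.01 against a background of 6.85. In the somatodendritic compartment Smn1 averaged 5.06 (SD 0.12, n = 3) with the knockdown and 5.20 (SD 0.18, n = 3) with the empty vector, a log2 difference of -0.14 (SE 0.11, limma adjusted p = 0.412). In the axonal compartment it averaged 5.32 (SD 0.40, n = 3) and 5.98 (SD 0.92, n = 3), a difference of -0.66 (adjusted p = 0.486). Without axonal empty vector replicate 1 the axonal difference was -0.14. At this signal a change of Smn1 was not detectable, and the probe set cannot show whether the knockdown worked.

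**Figure D2:**
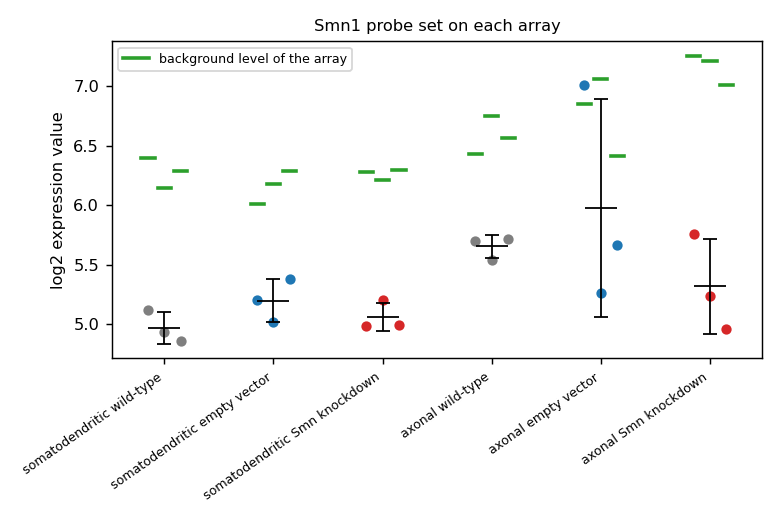
Log2 expression value of the Smn1 probe set on each of the 18 arrays (points), with the mean and SD of 3 arrays per group (black bars) and each array's background level (green lines). One array, axonal empty vector replicate 1 at 7.01, lies above its background level.

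The somatodendritic comparison of Smn knockdown with empty vector asks which transcripts of the cell bodies change with the knockdown. The 10 largest rises were all of interferon-induced genes. Ifit1, which binds viral RNA, rose by a log2 difference of 7.65 (SE 0.15, n = 3 per group), at least 52.1-fold. Rsad2, the antiviral enzyme viperin, rose 53.7-fold (log2 5.75, SE 0.16), from a mean of 7.27 to 13.02. Usp18, which removes ISG15 from proteins, was at least 35.3-fold higher. The guanylate-binding GTPases Gbp3 and Gbp6 were at least 38.1-fold and 16.8-fold higher, and the related GTPase Iigp1 at least 9.71-fold. Rtp4 was at least 28.3-fold, Ifi35 at least 22.5-fold, Ifi202b at least 16.9-fold and Oasl2, a relative of the oligoadenylate synthetases, at least 12.9-fold higher. With another probe set the log2 difference of Ifi35 was 1.10 instead of 5.93, and with wild-type arrays as the control that of Ifi202b was 2.74 instead of 4.54. For each of these genes all 3 knockdown arrays lay above all 3 empty vector arrays, which the rule for named genes required.

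All 34 measured members of the interferon and antigen presentation list rose, and all 34 did so adjusted over the list alone. Their median log2 difference was 3.08, or 2.86 with dim members at their bound. The list's mean level was 9.25 (SD 0.15, n = 3) with the knockdown, 5.84 (SD 0.10) with the empty vector and 6.20 (SD 0.04) in wild-type arrays, and against wild-type 33 of 34 rose. Camera called the list at adjusted p = 7.87e-50, and the call held with an estimated correlation (adjusted p = 0.0227). Markers of microglia and macrophages, the immune cells of nervous tissue, moved with it. Of 16, 15 rose, adjusted over all genes and over the list alone, with a median of 2.23 (camera adjusted p = 1.32e-17, and adjusted p = 0.0762 with an estimated correlation). Laptm5, a lysosomal protein of blood cells, rose 12.1-fold and Tyrobp, a signalling adaptor of myeloid cells, 7.53-fold. Ptprc (CD45) was at least 9.78-fold and the lysosomal Cd68 at least 4.94-fold higher. The microglial list was low in the empty vector arrays themselves. Its mean level was 6.29 (SD 0.16, n = 3) there, 7.90 (SD 0.03) in wild-type and 8.39 (SD 0.17) in knockdown arrays, and against wild-type its median difference was 0.52, with 10 members higher and 1 lower.

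**Figure D3:**
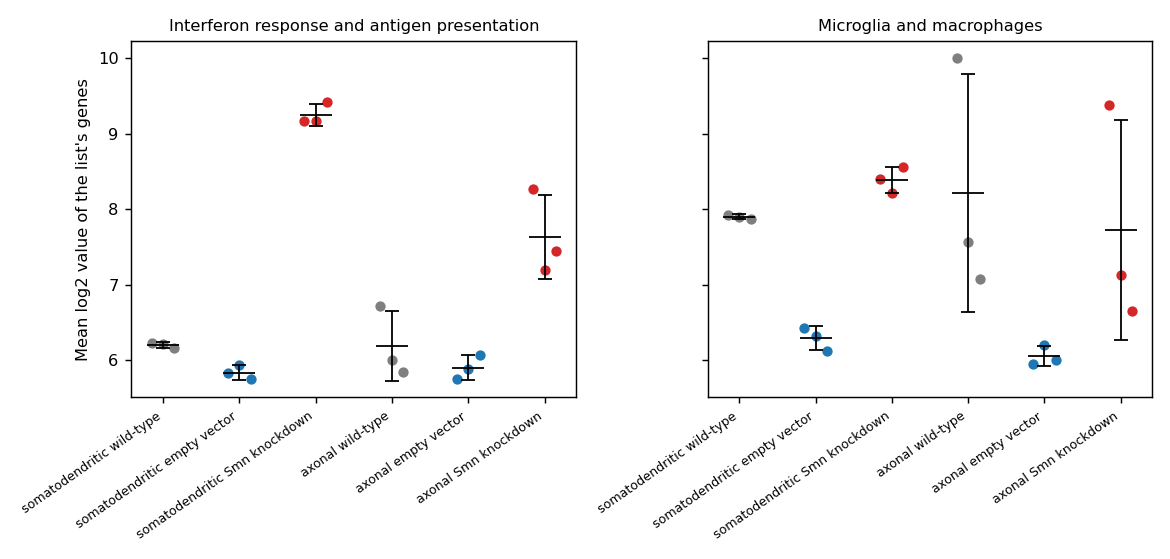
Mean log2 value of the 34 interferon and antigen presentation genes (left) and the 16 microglial and macrophage genes (right) on each array, by group. Points are arrays, and black bars are the mean and SD of 3 arrays. In the somatodendritic arrays the interferon list lies at 9.25 with the knockdown against 5.84 and 6.20 in the controls, while the microglial list is lowest with the empty vector, at 6.29; the compartments were normalized separately.

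Among the 10 largest falls in the same arrays, Acta2, smooth muscle actin, fell 22.3-fold (log2 -4.48, SE 0.33), but with probe sets that may read several genes left out another probe set stood for it and its difference was -0.16. Jam2, a junctional adhesion molecule, fell 7.66-fold (log2 -2.94, SE 0.13), and Pdgfra, a growth factor receptor of oligodendrocyte precursors and fibroblasts, 6.25-fold (log2 -2.64, SE 0.44). The collagen chains Col8a1 and Col11a1 were at least 9.52-fold and 5.39-fold lower. The serine protease Prss23 was at least 7.87-fold, the secreted Ecrg4, Ccn1 and C1qtnf3 at least 5.32-fold, 4.77-fold and 3.49-fold, and the adhesion receptor Adgrg6 at least 3.06-fold lower. With other probe sets the log2 difference was -1.53 instead of -2.44 for Ccn1, -1.26 instead of -2.42 for Ecrg4 and -0.79 instead of -2.40 for Adgrg6. Of 32 cell cycle genes 24 fell, 29 adjusted over the list alone, with a median of -1.03 (camera adjusted p = 7.93e-14, and adjusted p = 0.339 with an estimated correlation). Among them the centromere protein Cenpf fell 3.34-fold and the topoisomerase Top2a 3.39-fold. The kinase Bub1 was at least 2.34-fold lower.

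Of 13 astrocyte markers 9 fell, also over the list alone (median -0.49, camera adjusted p = 1.27e-04, and adjusted p = 0.351 with an estimated correlation), among them the water channel Aqp4 by a log2 difference of -1.40 and the gap junction protein Gja1 by -1.32. Of 12 oligodendrocyte lineage genes 7 fell, also over the list alone, and the median was -0.67, or -0.11 with dim members at their bound. They included the transcription factors Olig1 (log2 -2.04, SE 0.26) and Olig2 (-1.75). Of 12 neural progenitor genes 5 fell, also over the list alone, such as Sox2 (-0.92), at a median of -0.27. Of 18 genes of fibroblasts and meningeal cells 7 fell, 8 adjusted over the list alone, at a median of -0.26, or 0.00 with dim members at their bound. Camera adjusted p was 0.00677 for the oligodendrocyte and 0.0106 for both other lists, and with an estimated correlation the adjusted p = 0.425, 0.494 and 0.334. The progenitor call ended with wild-type arrays as the control, and the progenitor and oligodendrocyte calls ended among the brighter genes.

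Smaller shifts went upward. Of 72 oxidative phosphorylation genes 18 rose and 1 fell, also over the list alone, at a median of 0.19 (camera adjusted p = 2.60e-05, and adjusted p = 0.554 with an estimated correlation), such as the complex II subunit Sdhc (1.01) and the ATP synthase subunit Atp5b (0.89). Of 21 genes of the unfolded protein and amino acid stress response 10 rose, 11 over the list alone, at a median of 0.27, or 0.16 with dim members at their bound (camera adjusted p = 5.65e-04, and adjusted p = 0.258 with an estimated correlation). They included Herpud1 (0.79), which serves degradation from the endoplasmic reticulum, and the chaperone Hsp90b1 (0.76). Of 34 cytoskeletal genes 8 rose and 2 fell, 11 and 3 over the list alone, at a median of 0.16 (camera adjusted p = 0.0215, and adjusted p = 0.494 with an estimated correlation). The kinesin Kif5b rose by 1.09 and the neurofilament Nefl fell by 0.46. The cytoskeletal call ended among the brighter genes.

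Lists on axons and synapses had members changed in both directions and were not called. Of 60 genes of axon growth and guidance 6 rose and 22 fell, 8 and 23 over the list alone (camera adjusted p = 0.0667). The netrin receptor Dcc fell by 1.28, the microtubule protein Dcx by 1.18 and the actin regulator Enah by 0.95. Without somatodendritic empty vector replicate 1 camera called this list. Of 46 presynaptic genes 8 rose and 11 fell, 9 and 12 over the list alone. The falls included the active zone scaffolds Erc2 (-1.75) and Pclo (-1.07) and the vesicle GTPase Rab3c (-1.42). The median was 0.05, the mean -0.04, and fry called the list lower. Of 30 postsynaptic genes 5 rose and 6 fell, also over the list alone, among them Gphn, the scaffold of inhibitory synapses (-2.13), and Homer1 (-1.09). The median was 0.05 and the mean -0.07. Of 20 genes of the SMN complex and snRNP assembly, which builds spliceosome particles, 3 rose and 2 fell, also over the list alone, such as the Sm protein Snrpd3 (1.07).

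The other lists were not called by camera either. Rises and falls numbered 6 and 3 of 44 cytosolic ribosomal protein genes, 4 and 3 of 34 translation factors, and 6 and 4 of 27 axonal RNA-binding protein genes, where Stau2, a transport factor of RNA granules, fell by 1.16. They numbered 5 and 5 of 24 p53 targets, with the cell cycle inhibitor Cdkn1a at 0.68, and 3 and 1 of 9 nuclear-retained long noncoding RNAs, with Malat1 at 1.49. Of 14 immediate early genes 4 fell, such as Fos by 1.27 and Jun by 0.91. Among cholinergic motoneuron markers 1 rose and 4 of 15 fell, such as the transcription factor Foxp1 by 0.81. Markers of other spinal neurons (1 up and 1 down of 12), sensory neurons (1 up of 8), Schwann and neural crest cells (1 up and 3 down of 10), endothelial cells (1 down of 12) and erythroid cells (1 up of 7) changed little. Adjusted over each list alone the counts of rises and falls were the same for 8 of these 12 lists. They were 3 and 1 for translation factors, 6 and 5 for p53 targets, 4 and 1 for the noncoding RNAs, and 0 for erythroid cells.

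In total limma called 5088 of 18191 genes in this comparison, 2267 higher and 2821 lower, 627 of them by at least 2-fold, and the named genes had adjusted p from 1.46e-11 to 6.97e-04. Over all 18191 genes, called or not, the groups did not overlap in 7871 (43.3%), where chance alone gives 10% with 3 arrays against 3. A single fit to all 18 arrays, whose estimate of spread includes the axonal arrays, called 103 genes, and of the 10 named falls C1qtnf3 alone. Of 3176 called genes with several probe sets, 243 had another probe set called the opposite way.

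The axonal comparison of Smn knockdown with empty vector asks which axonal transcripts change with the knockdown. Erc2, a scaffold of the presynaptic active zone, fell from a mean of 10.04 to 4.73 (log2 -5.31, SE 0.39, n = 3 per group, limma adjusted p = 0.00569), at least 7.37-fold. Gphn, the scaffold of inhibitory synapses, was at least 4.03-fold lower (log2 -4.68, SE 0.52). Other large falls were of Cpsf3, which cuts pre-mRNA at its 3' end (at least 8.97-fold), the Ras pathway inhibitor Spred2 (8.09-fold), the ubiquitin enzyme Ube2h (7.94-fold) and the Hsp70 relative Hspa13 (7.02-fold). Fbxl17, a part of a ubiquitin ligase (at least 4.63-fold), the chromatin remodeller Chd6 (4.11-fold), Rpl7l1 (3.81-fold) and the protocadherin Pcdhb17 (1.76-fold) also fell. The 3 rises were of Gbp3, an interferon-induced GTPase (at least 8.72-fold, log2 4.58, SE 0.54), the prefoldin subunit Pfdn1 (6.66-fold) and Sema3f, a secreted guidance cue (3.94-fold). For each of these 13 genes the arrays of the groups did not overlap, which the rule for named genes required.

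By list, the interferon genes lay higher in the axonal knockdown arrays, with a median of 1.53 (camera adjusted p = 1.61e-09, and adjusted p = 0.403 with an estimated correlation). Gbp3 alone of 34 passed over all genes and 17 rose adjusted over the list alone. But 23 were near background in both groups and counted as 0, so that the median with dim members at their bound was 0.00 by construction. The microglial list lay higher at a median of 1.68 (camera adjusted p = 0.00368, and adjusted p = 0.576 with an estimated correlation), with 0 of 16 called by limma, 2 over the list alone. Since 11 of its genes were near background in both groups and counted as 0, the list had a median of 0.00 by construction with dim members at their bound. Its mean level on the knockdown arrays was 9.38, 7.13 and 6.65, the call ended without knockdown replicate 1 and without the 2 arrays least correlated with the somatodendritic controls, and with wild-type arrays as the control its direction reversed. Cytosolic ribosomal protein genes lay higher by a median of 0.37, and 12 of 44 rose adjusted over the list alone. Rps9 (log2 2.21, SE 0.39, adjusted p = 0.0636), Fau (2.02) and Rps19 (1.85) were among them. Oxidative phosphorylation genes had a median of 0.31, and 3 of 72 rose over the list alone, Atp5e (1.98), Cox8a (1.51) and Ndufa3 (1.49). For these lists limma called 0 genes over all genes. Camera adjusted p was 3.93e-05 and 0.00742, and with an estimated correlation the adjusted p = 0.476 and 0.511. The oxidative phosphorylation call ended without empty vector replicate 2, without those 2 arrays and with wild-type as the control.

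The lists on synapses and axons lay lower in the axonal knockdown arrays. Of 46 presynaptic genes 1 fell, and 7 fell and 1 rose adjusted over the list alone (median -0.66). Besides Erc2, the vesicle protein Syn3 (log2 -5.52, SE 1.09, adjusted p = 0.0740), the phosphatase Synj1 (-3.24) and the scaffold Pclo (-2.85) had the lowest p. With the knockdown level at background Syn3 was at -3.30 and Synj1 at -3.09. Of 30 postsynaptic genes 1 fell, 4 over the list alone (median -0.76), with the glutamate receptor Gria1 at -3.90 (SE 0.64, adjusted p = 0.0608), or -1.05 with its knockdown level at background. Of 60 axon growth genes 0 were called by limma, also over the list alone (median -0.78). The lowest p were those of the guidance genes Efnb2 and Slit1 (1.39, SE 0.40) and of the microtubule protein Mapt (-2.68, SE 0.83). Efnb2 was near background in both groups, so no size is given, and Mapt was at -2.52 with its knockdown level at background. Translation factors had a median of -0.44, with 0 of 34 called, 1 higher and 3 lower over the list alone. The cap-binding protein Eif4e was at -2.93, or -2.04 with its knockdown level at background. For the 27 axonal RNA-binding protein genes the median was -0.48 and 0 passed, also over the list alone. Camera adjusted p was 0.00203, 7.80e-04, 0.00492, 0.00964 and 0.0271 in this order, and with an estimated correlation the adjusted p = 0.501, 0.448, 0.476, 0.476 and 0.403. Only 18 presynaptic, 26 axon growth and 4 postsynaptic genes were above background in both groups, and with dim members at their bound the medians were -0.03, 0.00 and 0.00, and -0.14 for translation factors and -0.03 for RNA-binding proteins. With wild-type as the control the axon growth and RNA-binding calls ended. Without empty vector replicate 3 the translation factor and RNA-binding calls ended, as did the latter without knockdown replicate 1, and among the brighter genes all but the postsynaptic call ended. Neural progenitor genes lay at a median of 0.81 in the same comparison, or 0.26 with dim members at their bound, with 0 of 12 called, 5 higher over the list alone (camera adjusted p = 0.0548, and adjusted p = 0.476 with an estimated correlation), and among the brighter genes camera called them (adjusted p = 0.0187).

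**Figure D4:**
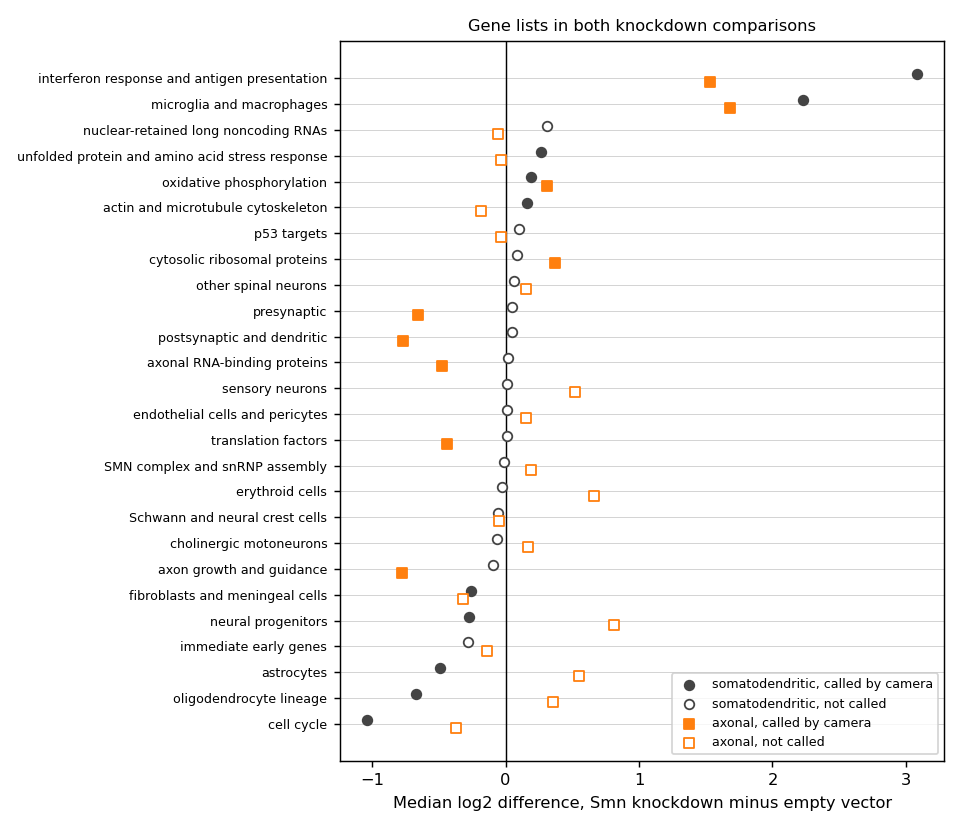
Median log2 difference between Smn knockdown and empty vector for the 26 gene lists (rows of the vertical axis), in somatodendritic (circles) and axonal arrays (squares). Filled symbols were called by camera with its preset correlation, and only the somatodendritic interferon call held with an estimated one. The interferon list lies at 3.08 and 1.53, the presynaptic list at 0.05 and -0.66; the axonal medians of p53 targets, stress response, noncoding RNAs and Schwann cells, all uncalled, change sign when each array is centred.

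In the axonal comparison limma called 32 of 18191 genes, 3 higher and 29 lower, and 3318 had an unadjusted p under 0.05. All 32 changed by at least 2-fold. Over all genes, called or not, 3958 (21.8%) had groups without overlap, against 10% by chance. Leaving out 1 array gave 4, 13 or 1 genes for empty vector replicates 1, 2 and 3, and 3, 190 or 4 for knockdown replicates 1, 2 and 3, and of the 13 named genes Erc2 alone passed in each of these. The count was 0 in a fit on the 6 arrays compared, 10 without the 2 arrays least correlated with the somatodendritic controls, 380 among genes above background, 743 against both controls together and 3763 in a fit to all 18 arrays. With probe sets that may read several genes left out, Cpsf3 was at -2.43 instead of -4.85, Ube2h at -1.23 instead of -4.68 and Sema3f at 1.67 instead of 1.98, and none of these 3 passed. With each array centred Sema3f, Spred2, Ube2h and Rpl7l1 did not pass, nor did these and Pfdn1 with wild-type as the control. Across genes, axonal and somatodendritic knockdown differences correlated weakly (r = 0.19, rho = 0.08, with genes not independent replicates). Called in both with the same direction were 16 genes, where 4.87 would be met by chance.

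The comparison of empty vector with wild-type in the somatodendritic compartment asks what the viral step changes without the hairpin. Transcripts of microglia were lower in the empty vector arrays. Csf1r, the growth factor receptor of microglia, fell 10.9-fold (log2 -3.44, SE 0.23, n = 3 per group, limma adjusted p = 4.20e-06). Ccl9, a chemokine, was at least 4.24-fold and Serpinb6b, a protease inhibitor, at least 1.75-fold lower. Of 16 microglial markers 12 fell, and all 16 adjusted over the list alone, at a median of -1.49, or -1.15 with dim members at their bound. Laptm5 fell 7.31-fold and Tyrobp 5.18-fold. Camera called the list at adjusted p = 3.86e-31, and the call held with an estimated correlation (adjusted p = 0.0353). The largest rises were smaller, 2.59-fold for the early response gene Fos, 2.05-fold for the microtubule-binding Clip3 and 1.81-fold for the mitochondrial ribosomal gene Mrpl24.

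Interferon genes also lay lower, 7 of 34 falling and 17 over the list alone, at a median of -0.27, or 0.00 with dim members at their bound. B2m, the light chain of class I antigen presentation, fell by 0.89. Markers of Schwann cells lay lower too, with 2 of 10 falling, also over the list alone, at a median of -0.15, or 0.00 with dim members at their bound. Slightly higher were the cytoskeletal list (3 of 34 rose, 10 rose and 1 fell over the list alone, median 0.12), noncoding RNAs (1 of 9, over the list alone 6 up and 1 down, median 0.41), presynaptic genes (2 of 46, 3 over the list alone, median 0.06) and translation factors (2 of 34, 6 over the list alone, median 0.09). Dync1h1, a motor protein, rose by 0.73 and the vesicle protein Sv2a by 0.82. Ribosomal protein (median 0.12) and oxidative phosphorylation genes (0.09) shifted with 0 genes called, and with 3 and 0 higher over the list alone. The largest of these camera adjusted p was 0.0366, for Schwann cells, and with an estimated correlation the adjusted p lay between 0.244 and 0.595. Leaving out 1 array ended the Schwann call (wild-type replicate 1, adjusted p = 0.116, or empty vector replicates 2 and 3), the oxidative phosphorylation call (wild-type replicate 2), the presynaptic call (wild-type replicate 3) and the noncoding RNA call (empty vector replicate 2). Among the brighter genes the presynaptic and Schwann calls ended.

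This comparison gave 364 genes by limma, 88 higher and 276 lower (75.8% lower), and 3138 at an unadjusted p under 0.05, and over all genes the groups did not overlap in 3435 (18.9%, against 10% by chance). With each array centred on its median 398 genes passed, 145 higher and 253 lower (63.6% lower). Without wild-type replicate 1, 2 or 3 the count was 200, 202 or 1408, without empty vector replicate 1 or 3 it was 212 or 221, and in a fit to all 18 arrays it was 7. Leaving out 1 array ended the call of Fos (wild-type replicate 2), of Clip3 (wild-type replicate 1, empty vector replicates 1 and 2) and of Mrpl24 (any array but wild-type replicate 3).

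In the axonal compartment the same comparison gave 0 genes by limma, with 603 at an unadjusted p under 0.05. The 5 genes with the lowest p were Vps13a, a lipid transfer protein (log2 4.02, SE 0.49), the ciliary gene Ttc30a1 (-2.83, SE 0.35), Ccdc30 (-2.68, SE 0.34), each at adjusted p = 0.234, the clock repressor Nr1d2 (2.40, adjusted p = 0.335) and Mto1, which modifies mitochondrial tRNA (-2.50, adjusted p = 0.634). Microglial genes lay lower at a median of -1.52, or -0.97 with dim members at their bound, 0 of 16 called and 2 over the list alone (camera adjusted p = 4.97e-09, and adjusted p = 0.547 with an estimated correlation), with Laptm5 at -4.14 (SE 1.10) and Csf1r at -4.52 (SE 1.38). The list's mean level was 10.01, 7.56 and 7.07 on the wild-type arrays and 6.05 (SD 0.13, n = 3) with the empty vector. Oxidative phosphorylation genes lay lower at a median of -0.23, with 0 of 72 called, also over the list alone (camera adjusted p = 1.61e-05, and adjusted p = 0.547 with an estimated correlation). The number of lists called rose from 2 to 5 and 8 without wild-type replicates 2 and 3, and to 4 without empty vector replicates 2 or 3. A fit to all 18 arrays called 53 genes.

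Axonal and somatodendritic arrays of the controls, wild-type and empty vector averaged, were compared to ask which transcripts make up more or less of the axonal RNA. The compartments were normalized separately, which affects every level and test across them. Transcripts of the ribosome were higher in axons, with Rps15 10.2-fold (log2 3.34, SE 0.15, n = 6 per compartment), Rps10 6.39-fold, Rps14 5.19-fold, Rplp0 5.05-fold and Rps24 4.25-fold. Of 44 cytosolic ribosomal protein genes 36 rose and 3 fell, also over the list alone, at a median of 0.89 (camera adjusted p = 7.03e-11, and adjusted p = 0.168 with an estimated correlation). Also higher were Bola2, of iron-sulfur handling (7.31-fold), Eif4ebp1, which restrains cap-dependent translation (5.78-fold), and Sars, the seryl-tRNA synthetase (5.23-fold). Dus2, a tRNA-modifying enzyme, was at least 48.8-fold higher, but its difference was 0.29 with another probe set, and Tk2 lay near background in both. With other probe sets the log2 difference was 1.44 instead of 2.53 for Eif4ebp1, 1.40 instead of 2.39 for Sars and 1.00 instead of 2.09 for Rps24.

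Markers of astrocytes and of the oligodendrocyte lineage were called lower in axons. Pdgfra was at least 25.5-fold lower (log2 -5.35, SE 0.40), the astrocytic bicarbonate transporter Slc4a4 at least 14.5-fold and Aqp4 at least 6.66-fold. Of 13 astrocyte markers 9 fell and 1 rose, also over the list alone, at a median of -3.02, or -1.95 with dim members at their bound. Of 12 oligodendrocyte genes 5 fell and 3 rose, also over the list alone (median -0.79, or -0.44 with dim members at their bound), and of 32 cell cycle genes 22 fell and 3 rose, also over the list alone (median -1.67, or -1.01). Neuronal and other transcripts among the 10 largest falls were the synaptic organiser Cbln4 (at least 11.8-fold), Vstm2a (15.3-fold), the ciliary gene Ttc30b (11.5-fold), Phf20l1 (8.40-fold), the chromatin regulator Setd5 (7.50-fold) and the hormone receptor Trhr (5.01-fold). Shisa9, a partner of AMPA receptors, was at least 7.93-fold lower, but rose by 0.82 with another probe set. Camera adjusted p was 2.65e-04 for astrocytes, 0.0265 for oligodendrocytes and 6.53e-05 for the cell cycle, and with an estimated correlation the adjusted p = 0.156, 0.156 and 0.195. The oligodendrocyte call ended among the brighter genes. Other non-neuronal markers were not lower on every axonal array. The microglial list averaged 10.01, 7.56 and 7.07 on the axonal wild-type arrays and 6.05 with the empty vector, against 7.90 and 6.29 in the somatodendritic groups. The fibroblast list averaged 8.60, 6.57 and 6.08 on the axonal wild-type and 6.01, 7.58 and 8.14 on the axonal empty vector arrays. Its somatodendritic means were 7.03 and 6.80.

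Camera called 7 lists on neuronal and general cell functions lower in axons, but each of these calls ended among the brighter genes, and all but that of axon growth ended when the 18 arrays were normalized together. Of 60 axon growth genes 35 fell and 9 rose (median -1.06), such as Dpysl2, which serves microtubule assembly (4.50-fold lower), and Stmn2 (3.36-fold lower). Of 46 presynaptic genes 26 fell and 4 rose (median -1.13), with Pclo 6.16-fold and Erc2 3.93-fold lower. Of 30 postsynaptic genes 12 fell and 3 rose (11 and 3 over the list alone, median -0.59, or -0.30 with dim members at their bound), with Map2, a dendritic microtubule protein, 2.49-fold lower. Of 27 axonal RNA-binding protein genes 15 fell, 16 over the list alone, and 3 rose, of 34 cytoskeletal genes 17 fell and 4 rose, and of 20 SMN complex genes 9 fell and 2 rose, such as Tgs1, which caps small RNAs (4.58-fold lower). Unless given, counts over the list alone were the same. Translation factors were called lower at a median of -0.31 (10 fell and 4 rose, 10 and 3 over the list alone), but the median was 0.15 when all 18 arrays were normalized together. Camera adjusted p lay between 5.50e-05 and 0.0444 for these 7 lists, and with an estimated correlation the adjusted p lay between 0.153 and 0.436. The translation factor call ended without somatodendritic wild-type replicate 3 (adjusted p = 0.0782), somatodendritic empty vector replicate 1 (0.0545), axonal wild-type replicates 1 (0.0504) and 2 (0.0557) or axonal empty vector replicate 2 (0.221), and the postsynaptic call without axonal wild-type replicate 1 (0.0504). Of 7 erythroid genes 6 lay higher, all near background.

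Limma called 11206 genes between the compartments of the controls, 6487 higher and 4719 lower in axons. By at least 2-fold 4337 changed, 574 higher and 3763 lower. The median over all genes was 0.18, and centring each array moved it by 0.15. Normalizing all 18 arrays together left 5924 genes, 3556 higher and 2368 lower. Of 5306 called genes with several probe sets, 1754 had another probe set called the opposite way. On simulated data this comparison made 33 wrong calls, more than the threshold on the adjusted p allows, so its gene count is uncertain.

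The same comparison in the knockdown cultures asks whether the axonal share of transcripts has this shape there. Ext2, which builds heparan sulfate, was 18.6-fold higher in axons (log2 4.21, SE 0.64, n = 3 per compartment) but -0.37 with another probe set. Mbd1, which binds methylated DNA, was 18.5-fold higher and Dus2 at least 91.2-fold, but only 0.88 on the log2 scale with another probe set. The F-box gene Fbxl17 was at least 16.7-fold, the sodium-calcium exchanger Slc8a1 at least 16.5-fold and the zinc finger gene Zscan21 at least 8.50-fold lower. Of 44 ribosomal protein genes 38 rose and 2 fell, also over the list alone, at a median of 1.12 (camera adjusted p = 1.17e-08, and adjusted p = 0.212 with an estimated correlation). Of 34 interferon genes 22 were lower in axons and 1 higher, 23 and 1 over the list alone, at a median of -1.58 (camera adjusted p = 2.79e-05, and adjusted p = 0.212 with an estimated correlation), with Oasl2 at least 6.47-fold lower. Of 46 presynaptic genes 26 fell and 3 rose, 27 and 3 over the list alone (median -1.81, camera adjusted p = 3.87e-05, and adjusted p = 0.212 with an estimated correlation), with Erc2 at least 8.28-fold lower. Axon growth (38 of 60 lower and 7 higher), postsynaptic (19 and 4 of 30, 21 and 4 over the list alone), translation factor (19 and 3 of 34), RNA-binding protein (17 and 3 of 27), cytoskeletal (20 and 3 of 34) and astrocyte genes (9 and 2 of 13) were called lower too, and 6 of 7 erythroid genes lay higher. Unless given, their counts over the list alone were the same, and with an estimated correlation their adjusted p lay between 0.0732 and 0.360. Among the brighter genes the calls of all 8 lists that lay lower ended. The astrocyte call ended without somatodendritic knockdown replicate 6 (adjusted p = 0.0615) or axonal knockdown replicates 1 (0.0832) and 2 (0.111). Limma called 11229 genes, 6189 higher and 5040 lower, and over all genes 12793 (70.3%, against 10% by chance) had groups without overlap. Differences between compartments correlated across genes with those of the controls (r = 0.82), and 8441 genes were called the same way in both, where independent lists would share 3514, against 76 the opposite way. Both comparisons share each gene's estimate of spread and the separate normalization, so they are not independent and 3514 is no fair baseline. Centring moved the median over all genes by 0.24. On simulated data this comparison made 35 wrong calls, more than the threshold on the adjusted p allows, so its gene count is uncertain.

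The interaction asks directly whether the knockdown effect differed between axons and cell bodies, on values normalized separately for each. The largest positive differences were of Bcan, a brain matrix proteoglycan (5.47, SE 0.81, n = 3 per group), the progenitor lipid carrier Fabp7 (4.97, SE 1.26) and Col11a1 (4.96, SE 1.28), and the largest negative ones of Minar2 (-5.76, SE 1.25), the adhesion protein Negr1 (-5.31, SE 1.11) and the Ras activator Rasgrf1 (-4.93, SE 0.80). With other probe sets Rasgrf1 was at 0.13, Bcan at 1.20 and Minar2 at -1.52, Rasgrf1 and Minar2 without a call. In axons 1 or both groups were below background for all 6, so these sizes are not exact. With the dim group at its bound they were 3.87 for Bcan, 4.50 for Fabp7, -3.53 for Minar2, -2.71 for Negr1 and -4.01 for Rasgrf1, and Col11a1 was dim in both axonal groups. With wild-type as the control Bcan was at 2.61, Fabp7 at 0.61 and Col11a1 at 3.35, and none of these 3 passed, while Fabp7 and Col11a1 also lost their calls when all 18 arrays were normalized together. The calls of Fabp7 and Col11a1 ended without any 1 of the 6 somatodendritic arrays, that of Fabp7 also without axonal knockdown replicate 1, that of Col11a1 without axonal empty vector replicate 1 and that of Minar2 without somatodendritic empty vector replicate 2. The interferon list had lower knockdown differences in axons, by a median of -1.64 (camera adjusted p = 5.72e-13, and adjusted p = 0.115 with an estimated correlation), with 11 of 34 members lower and 1 higher in axons, 16 and 1 over the list alone. Only 2 of the 34 were above background in all 4 groups, so a smaller rise in axons is not shown. Ccl5, a chemokine, differed by -3.23 and Oasl2 by -4.56, both of them dim in both axonal groups, so the sizes of their axonal changes are not known. Presynaptic genes, not called in the somatodendritic comparison, had lower knockdown differences in axons by a median of -0.81 (camera adjusted p = 0.00248, and adjusted p = 0.350 with an estimated correlation), with 6 of 46 lower and 1 higher, 7 and 1 over the list alone, and this call ended among the brighter genes. With dim members at their bound the median was -0.18. Erc2, at -3.56 (SE 0.39), was at -1.13 with its axonal knockdown level at background, and Gphn at 0.12 instead of -2.55, so for Gphn a larger fall in axons is not shown. In total limma called 1231 genes, 766 higher and 465 lower in axons. The count was 475, 416 and 471 without somatodendritic empty vector replicates 1 to 3, 524, 386 and 453 without somatodendritic knockdown replicates 4 to 6, and 2643 and 2355 without replicate 2 of axonal empty vector and of axonal knockdown. With wild-type as the control it was 1946, and with array weights 997, of which 432 were higher and 565 lower. On simulated data the interaction made 24 wrong calls, beside 11 and 45 correct ones for log2 changes of 1 and 2. That is more than the threshold on the adjusted p allows. The share of wrong calls among the 1231 genes may therefore exceed that threshold too.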

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

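The results in this part are those whose knockdown effect, knockdown against empty vector, differed between the axonal and the somatodendritic compartment by the interaction test at adjusted p under 0.05. They are 25 of 38 genes named by the rule and 12 of 26 lists. Over all 18191 genes 1231 passed this test. On simulated data it made 24 wrong calls, more than its threshold allows, so a gene that passed may be a wrong call more often than stated. Apart from Smn1, the 38 were picked for large changes in a knockdown comparison or in this test. The 6 picked for this test passed by selection, so the share of 25 in 38 is no result. Values are axonal minus somatodendritic log2 differences with n = 3 arrays per group, and the compartments were normalized separately. The tests of the lentiviral step, of the share of microglia, of separate handling (spikes and Gapdh), of dilution, the spike covariate without 1 array, the splits of arrays and the differences with dim groups at their bound were chosen only after the result was seen.

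Interferon-induced genes that rose in the somatodendritic compartment had lower knockdown differences in axons: Ifit1 by -4.73 (SE 1.09), Oasl2 by -4.56, Usp18 by -3.65, Iigp1 by -3.49 and Gbp6 by -2.60. Of genes that fell in the somatodendritic compartment, Col11a1 differed by 4.96, Pdgfra by 3.31 and C1qtnf3 by 2.34, with axonal differences of 2.18, 0.66 and -0.14, none of them called. Pfdn1 differed by 1.93 and Sema3f by 1.93. Genes lower in the axonal knockdown arrays differed by -4.91 (Spred2), -4.85 (Cpsf3), -4.63 (Fbxl17), -4.59 (Ube2h), -4.37 (Pcdhb17), -4.29 (Rpl7l1), -4.22 (Hspa13), -4.20 (Chd6), -3.56 (Erc2) and -2.55 (Gphn). These 10 were below background in the axonal knockdown arrays, so the sizes are not exact, and with that level at its bound they were, in the same order, -2.92, -3.17, -1.91, -2.90, -0.78, -1.88, -2.25, -1.76, -1.13 and 0.12, so for Gphn a larger fall in axons is not shown. The largest differences over all genes were those of Bcan (5.47) and Fabp7 (4.97) upward and Minar2 (-5.76), Negr1 (-5.31) and Rasgrf1 (-4.93) downward, or 3.87, 4.50, -3.53, -2.71 and -4.01 with the dim axonal group at its bound. The 5 interferon-induced genes, Col11a1, Pdgfra and C1qtnf3 were below background in both axonal groups, where a change would go unseen. With other probe sets Rasgrf1 was at 0.13, Bcan at 1.20 and Minar2 at -1.52, and with wild-type as the control Bcan was at 2.61, Fabp7 at 0.61 and Col11a1 at 3.35.

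Camera called 12 lists in the interaction, and with an estimated correlation it called 0. Their median differences were -1.64 for interferon, -0.81 for presynaptic, -0.74 for stress response, -0.73 for postsynaptic, -0.70 for axonal RNA-binding protein, -0.57 for axon growth, -0.51 for translation factor and -0.28 for cytoskeletal genes. They were 1.27 for oligodendrocyte, 1.11 for progenitor, 0.65 for cell cycle and 0.27 for ribosomal protein genes. With dim members at their bound, and at 0 where both groups were dim, they were -2.02, -0.18, -0.74, -0.21, -0.15, -0.06, -0.38, -0.28, 0.06, 1.11, 0.89 and 0.24 in this order. Only 2 of 34 interferon genes were above background in all 4 groups, and unread axonal changes count as 0, so -2.02 does not show a smaller rise in axons. Leaving out 1 array ended the calls of stress response (somatodendritic empty vector replicate 3, adjusted p = 0.0546, axonal empty vector replicate 3, 0.203, axonal knockdown replicate 2, 0.105) and of axon growth genes (axonal empty vector replicates 1, 0.0941, and 3, 0.0679, axonal knockdown replicates 1, 0.122, and 3, 0.0655). It also ended those of oligodendrocyte genes (somatodendritic empty vector replicate 3, 0.0519, axonal empty vector replicates 2, 0.0692, and 3, 0.0787, axonal knockdown replicates 1, 0.0547, and 3, 0.0550) and of cell cycle genes (axonal empty vector replicates 1, 0.226, and 2, 0.0761). The translation factor and RNA-binding calls ended without axonal empty vector replicate 3 (0.0787 for each), and the cytoskeletal call without axonal knockdown replicate 3 (0.0550). With wild-type as the control the ribosomal protein, axon growth, stress response and RNA-binding calls ended. Among the brighter genes the axon growth, presynaptic, postsynaptic, translation factor, RNA-binding, cytoskeletal, stress response and oligodendrocyte calls ended, with all 18 arrays normalized together the cell cycle, stress response and oligodendrocyte calls, and without the 2 axonal arrays least correlated with the somatodendritic controls the axon growth, cell cycle and oligodendrocyte calls. The interaction gave 1231 genes. Of 100 splits of the 12 arrays 2, the real one included, gave as many, and the highest other gave 1290. The splits exchanged knockdown and empty vector labels within each compartment, which also breaks up the somatodendritic knockdown effect. They therefore do not test the interaction alone, and chance as the source of the count is not excluded.

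The first pattern weighed is the rise of interferon genes with the knockdown. The tables argue against the lentiviral step, as done for the empty vector, as the whole cause. With the empty vector the list was lower than in wild-type arrays, at a median of -0.27 (between -0.43 and -0.14 over the 9 pairs of arrays). But the microglial list was lower there too, at a mean of 6.29 against 7.90, which may hide a smaller rise. The tables also argue against a larger share of microglia as the whole cause, since against wild-type arrays the interferon list rose by 2.09 more than the microglial list (1.83 to 2.36 over the pairs of arrays). Separate handling of the knockdown arrays stays open: the gap between the BioC and BioD spikes and BioB was larger by 0.21 in the somatodendritic knockdown than in the empty vector arrays, the difference between the 3' and 5' probe sets of Gapdh was 4.04 against 3.61, without overlap, and the titles of all knockdown arrays follow another scheme than those of all controls, so that a batch would be the same as the group. A response to the hairpin or its virus preparation and one to the loss of Smn may both raise these genes, and with 1 hairpin they cannot be told apart.

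The second pattern is the fall of 29 genes, among them Erc2 and Gphn, in the axonal knockdown arrays. Dilution by RNA of other cells may contribute and stays open, since 18 abundant neuronal transcripts had a median of -0.45, but from -1.77 to 0.07 over the 9 pairs of arrays. Progenitor genes lay at a median of 0.81 (0.26 with dim members at their bound), Fabp7 at 5.02 and Bcan at 4.71, none of them called. With the empty vector level at background Fabp7 was at 4.55 and Bcan at 3.11. In empty vector replicate 2, the control array with the same signs of low input, the 29 genes that fell lay at 0.28 against wild-type, which decides nothing, since they were chosen as higher on the empty vector arrays, this one among them, and it is 1 array. With the spike level as a covariate 100.2% of the median difference was kept (-3.62 before and after) and 29 of 29 genes were still called. But this level, of the BioC and BioD spikes, differed by only 0.09 between the axonal knockdown and empty vector arrays. A covariate so alike in both groups can remove little whatever its slope, so the share kept decides nothing. Empty vector replicate 2 gave 52.7% of the spread of the spikes within groups. Without it 92.7% was kept (-3.76 before and -3.48 after) and the genes called went from 6 to 0. Less labelled RNA, whether or not the spikes follow it, stays open. The BioB spike was not alike in both groups, at 10.84 (SD 1.55) in axonal knockdown and 12.30 (SD 1.13) in axonal empty vector arrays. The gap between the BioC and BioD spikes and BioB was 2.94, 4.06 and 0.95 on the knockdown arrays. On the empty vector arrays it was 1.23, 0.64 and 1.42. Separate handling of the knockdown arrays therefore stays open for this pattern too.

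Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real value and the highest of the other splits were 5088 and 0 genes for the somatodendritic knockdown comparison (1 split with as many), 32 and 16 for the axonal one (1 split), 364 and 2 for the somatodendritic empty vector comparison (1 split), 0 and 1 for the axonal one (10 splits), and 11229 and 0 between the compartments with the knockdown (1 split). For the controls, taken as 2 groups of 6, the real split gave 11366 genes and the highest other 125, with 1 of 100 splits as large. Every other split mixed compartments that had been normalized apart. The outcome was therefore largely fixed in advance and decides nothing about chance.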

How the results depend on the processing

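Chosen only after the result was seen were the spike covariate, leaving out 2 axonal arrays, the restriction to genes above background and the list tests under other scalings. Signal over background and 3 arrays per group limit the axonal results. Over all alternatives 197 counts and target levels were taken as unchanged and 71 moved. A count was unchanged within 1.5 times, and Smn1, never called, was taken as unchanged whatever its value. Of values of named genes 1423 were taken as the same, 162 lost the call, 5 gained it and 3 reversed, and of single lists 2226, 179, 79 and 5. The same means that direction and call were kept, or that neither fit gave a call, whatever the direction. Smn1 in the axonal empty vector comparison, at -0.19 to 0.76, was taken as the same. Unless fewer genes or arrays were tested, the cause was not tested.

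All probe sets gave 9255 (somatodendritic knockdown), 59 (axonal knockdown), 1 (axonal empty vector), 28509 and 26615 (between compartments, controls and knockdown) and 2558 genes (interaction), as more features were tested. The brighter genes alone gave 62 (axonal knockdown), 212 (somatodendritic empty vector), 4638 and 5495 (between compartments, controls and knockdown) and 605 genes (interaction), as fewer were tested. At least 2-fold changed 627 (somatodendritic knockdown), 101 (somatodendritic empty vector) and 4337 genes (compartments of controls). One fit to all 18 arrays gave 103 and 3763 (somatodendritic and axonal knockdown) and 7 and 53 (empty vector). The 6 arrays compared gave 0 (axonal knockdown, limma, 3318 genes with unadjusted p under 0.05 in the 9-array fit) and 209 (somatodendritic empty vector). Quantile normalization of all arrays together gave 76 (axonal knockdown) and 5924 (compartments of controls).

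For the axonal knockdown comparison centring gave 13, trend and robust 17, wild-type as the control 18, both controls 743, the spike covariate 84, leaving out 2 arrays 10 and genes above background 380. With the title number as a block, which takes arrays as pairs though the numbers do not pair them, it gave 0. The interaction gave 1946 with wild-type as the control and 3024 without 2 arrays.

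Leaving out 1 array gave 3719 to 4647 genes (somatodendritic knockdown), 1 to 190 (axonal knockdown), 200 to 1408 and 0 to 0 (empty vector), 10012 to 11369 and 9691 to 11138 (compartments) and 386 to 2643 (interaction). Smn1 ranged from -0.23 to -0.05 in the somatodendritic and from -1.02 to -0.14 in the axonal compartment. Lists called numbered 10 to 12, 7 to 11, 8 to 11, 3 to 8, 10 to 13, 9 to 10 and 7 to 13 in the same order.

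With an estimated correlation camera called 1 list for the somatodendritic knockdown, 1 for the somatodendritic empty vector comparison and 0 for the other 5. Fry called 2 (axonal knockdown), 1 and 0 (empty vector) and 16 (compartments with knockdown). The brighter genes gave 4, 2 and 5 lists (compartments of controls, with knockdown, interaction), and common quantile normalization 6 (compartments of controls).

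Reversed were Shisa9 (0.82), Ext2 (-0.37) and Rasgrf1 (0.13) with another probe set. For lists, with the sign of the direction before the adjusted p, reversed were presynaptic genes by fry (-0.0142, somatodendritic knockdown), microglia with wild-type as the control (-0.615, axonal knockdown), translation factors among brighter genes (0.563) and with common quantile normalization (0.934, compartments of controls), and oxidative phosphorylation with wild-type as the control (-0.0284, interaction).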

Other observations

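The lists and tests in this part were chosen only after the result was seen, except the second microglial list, whose prediction was written before. In the somatodendritic knockdown arrays 13 of 14 genes of class I antigen presentation and the immunoproteasome rose, at a median of 2.18 (camera adjusted p = 0.0151 with an estimated correlation), among them the proteasome subunits Psmb8 (log2 3.29) and Psmb9 (2.98), the regulator Nlrc5 (3.06) and B2m (3.13). This list was picked after the interferon list had been called and is not independent of it: 6 of its 14 genes, B2m and both subunits among them, belong to that list, and of the 8 others 7 rose, at a median of 1.38. Of 20 chemokine and complement genes 12 rose, at a median of 0.83 (adjusted p = 0.0059 with an estimated correlation), with the chemokines Ccl5 (3.43, or 2.67 with its empty vector level at background) and Cxcl10 (2.26) and the complement subunit C1qb (2.77). Of these 20 genes 5 belong to the interferon or the microglial list, those 3 among them, and of the 15 others 7 rose, at a median of 0.31. The same list was lower with the empty vector than in wild-type arrays, where 5 of its genes fell (adjusted p = 0.0268 with an estimated correlation), C1qb by -1.91, so that the control of this comparison was itself low. Of 24 genes of the standard proteasome 12 rose, at a median of 0.27 (adjusted p = 0.142 with an estimated correlation). Of 20 contractile and matrix genes 10 fell and 2 rose, at a median of -0.56 (adjusted p = 0.243 with an estimated correlation), such as the matricellular Ccn2 (-1.86) and the myosin light chain Myl9 (-0.89).

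The pattern weighed here is the lower level of microglial transcripts in the somatodendritic empty vector arrays. Each number in the array titles holds arrays of both groups, so a batch that follows the numbers falls on both alike and could not give this difference. Within each number the list was lower with the empty vector, by -1.63, -1.40 and -1.69, which is no further test. A batch that follows the groups cannot be told apart from the vector. Fewer microglia in the empty vector cultures may be the source and stay open, and no biological explanation was tested. A second microglial list had a median of -0.37, and 8 of its 19 genes fell. By the prediction written before, a median this small goes against fewer microglia, though the pairs of arrays, from -0.56 to -0.25, lay on both sides of the limit set. Only 6 of the 19 were above background in wild-type arrays, and genes near background have no room to fall, so the list could hardly meet the prediction. Those 6 had a median of -1.27. But they were picked as high in wild-type arrays, which favours a fall, so their median does not rescue the prediction. Over 18 abundant neuronal transcripts the median was 0.27 higher with the empty vector, with 1 gene called (camera adjusted p = 1.05e-07, and adjusted p = 0.0448 with an estimated correlation).

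The contractile and matrix genes lower in the somatodendritic knockdown arrays may come from fewer fibroblast-like cells, which stays open. The fibroblast and meningeal list had a median of -0.26 (-0.49 to -0.17 over the pairs of arrays), but 8 of its 18 genes were above background on all empty vector arrays, with a median of -0.87, and the others have little room to fall.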
